A study of Taeniopygia guttata with 22 samples.

How the data were processed

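The series holds RNA sequencing of the song nucleus RA of zebra finches, laser-captured from cresyl violet stained sections and amplified with SMART-Seq v4 from 1 ng of RNA, per the labels. The 22 libraries come from 5 females and 5 males at 20 days posthatch and from 7 females and 5 males at 50 days. Replicates were taken as the labels number them, each with its own brain id. The deposited values are raw read counts per gene, a whole number for each library, and no normalisation was applied to them before they were deposited. Reads were trimmed with Trimmomatic 0.36, checked with FastQC 0.11.9 and aligned with STAR 2.6.1, per the submitters' processing notes. The counting tool, genome build, annotation and strand setting are not given in the sources used here. PCR copies were not removed with molecular identifiers, so a limit worked out from counts covers counting error only.

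The table holds 21955 entries, of which 169 carry no gene ID. Those took 0.0344% to 0.0739% of the counts of a library and were left out. Of the 21786 genes with an ID 20923 had at least 1 count, and 16004 passed the edgeR filter on low counts and were tested. Chromosome class was read from the table of the bTaeGut7.mat assembly, which may not be the assembly the reads were aligned to. It matched 16205 genes holding 96.9% of the counts, and 13585 of those tested. Of the tested genes 12921 are autosomal, 658 (4.11%) Z-linked, 6 W-linked and 2419 without a class, and 11839 have a symbol. Total counts were 16.17 M to 65 M per library, with 9 libraries above a limit of 40 M set at the gap between the sets.

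Libraries were scaled by the trimmed mean of M-values (TMM). A quasi-likelihood model with the 4 groups was fitted with edgeR 4.0.16 in R 4.3.3. The contrasts were male against female at each age, 50 against 20 days within each sex, and the interaction, which is the male age change minus the female one. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Fold changes are on the log2 scale, with a standard error (SE), and levels are counts per 1e6 counts (CPM) scaled by TMM, as mean ± SD. A fold against a group with no counts is given as a lower limit, with 3 counts over the whole group as its floor. The fitted folds of SIX2, UCN3 and HAPLN2 are no such bound.

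The 30 gene lists, with 1086 members of which 948 were in the table and 920 tested, were fixed before the data were examined, as were the contrasts, the tests and the rule for naming genes. They cover potassium channels, sodium channels, calcium channels and calcium-binding proteins, glutamate receptors, and GABA and glycine receptors. Neuronal lists are of GABAergic interneuron markers, projection neuron markers, synaptic vesicle genes, neurofilaments and axonal cytoskeleton, immature neuron markers and axon guidance. Further lists are of myelin, oligodendrocyte precursors, astrocytes, microglia, endothelial and mural cells, fibroblasts, red blood cells, and perineuronal nets and extracellular matrix. The rest are of steroid and thyroid signalling, growth factors, cell death, cell cycle, oxidative phosphorylation, glycolysis, cholesterol synthesis, ribosomal proteins, immediate early genes, stress genes and Z-linked genes by synteny. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, adjusted over the 30 lists of a contrast. Counts "over the list alone" adjust p over the members of that list.

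Genes are named by a fixed rule with 3 parts. The first takes the 6 called genes with the largest rise and the 6 with the largest fall in each contrast, with a mean of at least 5 CPM, a symbol and, except for the interaction, no overlap between the groups. The next takes the 3 called members of each list with the smallest p. The last is a fixed set that holds ESR1, CYP19A1, GHR, NTRK2, BDNF, SCN3B, SCN4B, KCNC1, PVALB, SLC17A6 and GAD1. Some genes named by the rule are not reported here. A gene named in one contrast is in places shown in another by its mean. The Z score of a library is the median of log2(CPM+1), centred over the libraries, of Z-linked genes minus that of autosomal genes, and the sexes were compared by an exact permutation test.

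Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, another scaling, no filter or a stricter one (1 CPM in 5 libraries), a replicate block, leaving out each library, summing the libraries of female 50-day replicates 5 and 6, a fit of only the groups compared, a fold limit and an adjusted p under 0.01. After the data were seen the depth set as a model term, fits of the shallow or the deep libraries alone, thinning to the smallest library, robust dispersions, the Z score from the synteny list and the overlaps without each library were added. The steps were tested on simulated counts with 200 changed genes. For the sex difference at 50 days edgeR recovered 42% of 1.5-fold and 70% of 2-fold changes, at 20 days 30% and 61%, for age in males 32% and 58%, for age in females 46% and 70%, and for the interaction 7% and 46%. The share of false calls was 0% to 9.09% with the main edgeR fit and 13.4% to 22% with DESeq2. Counts were drawn once per contrast, with independent genes and the spread that edgeR had estimated, so these shares do not rank the methods.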

Results

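RNA was measured in RA, the robust nucleus of the arcopallium, which is the motor output nucleus of the song circuit of songbirds. In zebra finches males sing and females do not, and RA is far larger in adult males. The nucleus was cut from frozen, stained sections by laser capture, and its RNA was copied into cDNA and sequenced as 22 libraries. They fall into 4 groups, with 5 females and 5 males at 20 days posthatch, and 7 females and 5 males at 50 days. The birds were killed soon after the lights came on, with no singing seen, per the labels. The design asks when, between early song learning and vocal practice, the transcriptomes of the male and the female nucleus come apart.

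Total counts ran from 16.17 M to 65 M per library. They fell into a shallow set of 13 libraries (16.17 M to 22.35 M) and a deep set of 9 (49.12 M to 65 M). All 5 female libraries at 20 days were deep and all 5 male libraries at 20 days were shallow, so depth and sex cannot be told apart at that age within a set. At 50 days 1 of 7 female and 3 of 5 male libraries were deep. Between deep and shallow libraries of the same group, where only the 50-day groups hold both, the smallest adjusted p of any gene was 1 with edgeR, and 530 of 16004 genes had an unadjusted p under 0.05. Within groups, log2 expression correlated across genes with r from 0.947 to 0.981. The highest value belonged to female 50-day replicates 5 and 6, whose brain ids share a number; they may be samples of 1 bird, in which case p-values at 50 days are too small. Female 20-day replicates 4 and 5, whose ids do not, came close with 0.978 (the next value in that group was 0.967), so such a correlation does not by itself mark 1 bird. The counts of the 50-day pair differed by more than sampling noise (chi-square of 24.92 per gene). They are thus not 1 library deposited a second time. That value was still the lowest of any pair within a group, and the next was 36.83, for male 20-day replicates 2 and 5. Female 20-day replicates 4 and 5, both deep, gave 67.73. Female 50-day replicate 6 gave 66.58 to 91.34 with the other libraries of its group. The 50-day pair was thus the closest by this measure, which does not show whether replicates 5 and 6 are 1 bird. They were kept as separate libraries, as the labels number them, and summed as an alternative.

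Male birds carry ZZ and female birds ZW sex chromosomes, and the Z-linked genes separated the sexes in every library. The median of Z-linked genes relative to autosomal genes, on a centred log2 scale, was 0.341 ± 0.0237 (SD, n = 5) in males and -0.268 ± 0.0166 (SD, n = 5) in females at 20 days. The difference of 0.609 had an exact two-sided permutation p of 0.00794, the smallest this design can give. At 50 days the medians were 0.342 ± 0.038 (SD, n = 5) and -0.271 ± 0.0249 (SD, n = 7), a difference of 0.613 (exact permutation p = 0.00126, again the smallest possible). Among shallow 50-day libraries the means were 0.328 for 2 males and -0.266 for 6 females, and among deep ones 0.351 for 3 males and -0.303 for 1 female. With the list of Z-linked genes taken from conserved synteny in place of the reference table, the differences were 0.618 and 0.585. The 6 tested genes classed as W-linked overlapped between the sexes and did not separate them. Males carry no W chromosome, so the counts read for these genes in males do not come from a W copy.

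**Figure D1:**
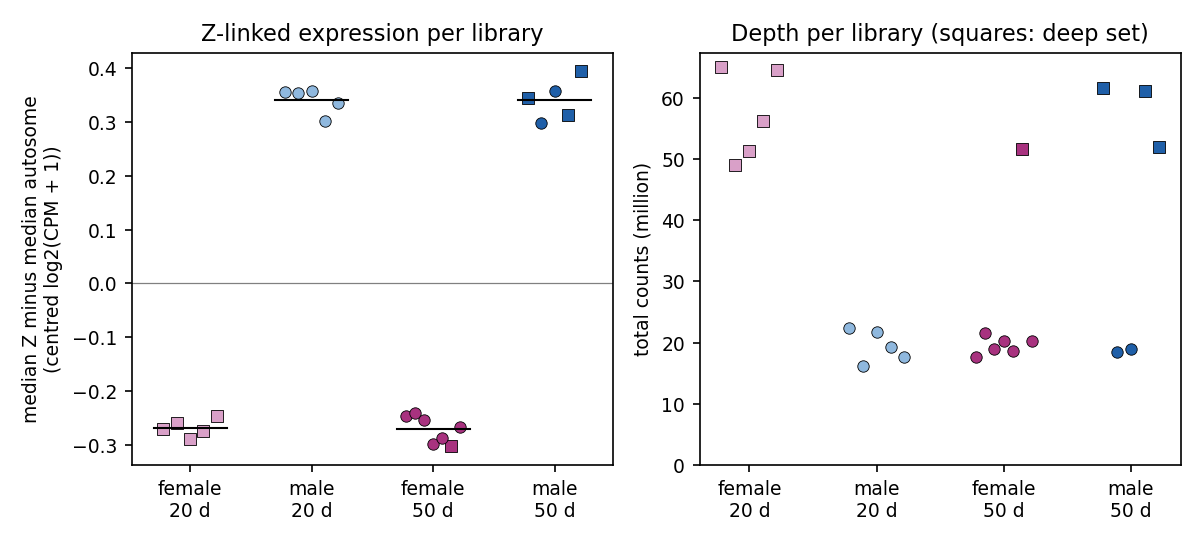
Left, Z-linked relative to autosomal expression of each library (difference of medians, centred log2 CPM) by group, with the group mean as a line; males lie between 0.298 and 0.394 and females between -0.303 and -0.242. Right, total counts per library, with squares for the deep set; the 5 female 20-day libraries are all deep and the 5 male 20-day libraries all shallow.

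At 20 days the sexes differed mainly at genes of the Z chromosome, which were higher in males. F2R, the thrombin receptor, was 2.58-fold higher in males, and ITGA2, an integrin subunit for collagen, 2.38-fold (log2 fold changes 1.37, SE 0.24, and 1.25, SE 0.16; adjusted p = 0.000685 and 1.15e-05). HSD17B4, a peroxisomal enzyme of fatty acid and steroid metabolism, was 2.06-fold higher (adjusted p = 2.84e-09), and RPS6, a protein of the small ribosomal subunit, 2.08-fold (adjusted p = 3.56e-08). NTRK2, the receptor of BDNF, stood at 600.3 ± 91.6 CPM (SD, n = 5) in males and 360.2 ± 35.2 CPM (SD, n = 5) in females (adjusted p = 2.48e-05).

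In all, 337 of 16004 genes (2.11%) differed by sex at 20 days, 308 higher and 29 lower in males. Of the 308 higher genes 281 lay on Z, against 658 of the genes tested (Fisher exact test, two-sided, odds ratio 590, log10 p = -373). The median Z-linked gene was 0.69 higher in males on the log2 scale, with the middle quartiles from 0.35 to 0.96. Other Z-linked genes with large folds were the glyoxylate reductase gene GRHPR (2.38-fold), RMI1 (2.37-fold) and MED18 (2.35-fold), and the centromere gene CENPK was 1.94-fold higher. Among the genes named by the rule the autosomal glycosyltransferase gene GBGT1 had the largest fold, 4.08 (log2 fold change 2.03, SE 0.43, adjusted p = 0.00659). Of the 29 genes lower in males 27 were autosomal, and 6 of the 29 were at least 2-fold lower. Those named by the rule had smaller folds. PAWR fell by 0.79 on the log2 scale (adjusted p = 0.0408), SLC35F5 by 0.73 and FILIP1L by 0.68. PAK6 fell by 0.56, PAIP2B by 0.51 and DIS3L by 0.49. PAWR lost its call in 9 of the 22 fits that leave out 1 library (adjusted p up to 0.123), DIS3L in 6 (up to 0.11) and PAIP2B in 3 (up to 0.0551).

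The hormone, channel and transmitter genes of the fixed set reported here, other than NTRK2, were not called at 20 days. For the oestrogen receptor ESR1, aromatase (CYP19A1), GHR, BDNF, SCN3B, SCN4B, KCNC1, SLC17A6 and GAD1 the adjusted p ran from 0.765 for GAD1 to 0.978 for ESR1. PVALB, which encodes the calcium buffer parvalbumin, stood at 1015 ± 317 CPM (SD, n = 5) in males and 682 ± 288 CPM (SD, n = 5) in females (adjusted p = 0.368, but 0.0375 without female 20-day replicate 3).

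Of the 30 fixed gene lists 5 passed at 20 days, all higher in males, and 1 of them held with an estimated correlation. That was the list of Z-linked genes by synteny, with 54 of 108 members called higher, 54 not called and 79 higher when adjusted over the list alone (camera adjusted p = 2.86e-75, and adjusted p = 4.43e-09 with an estimated correlation). Cholesterol synthesis had 2 members higher, HMGCS1 (1.60-fold) among them, and 1 lower, SQLE (log2 fold change -0.45), of 20, with the same counts adjusted over the list alone (camera adjusted p = 0.00109, and adjusted p = 0.556 with an estimated correlation). SQLE kept its call in only 6 of the 22 fits without 1 library, with an adjusted p up to 0.146. Growth factor signalling had 2 of 58 members higher, NTRK2 among them, and 3 adjusted over the list alone (camera adjusted p = 0.0468, and adjusted p = 0.556 with an estimated correlation). Astrocyte markers (camera adjusted p = 0.0468, and adjusted p = 0.932 with an estimated correlation) had no member called over all genes and 1 higher over the list alone. Cell cycle genes (camera adjusted p = 0.0468, and adjusted p = 0.932 with an estimated correlation) had none by either count. Both lists passed on the balance of members that were not called one by one over all genes. These lists and growth factor signalling lost their call in 6 (astrocyte) or 7 of the 22 fits without 1 library. Genes of oxidative phosphorylation did not pass as a list (camera adjusted p = 0.337), and the 3 members called higher of 57 were all Z-linked, among them NDUFS4 (1.99-fold) and ATP5ME (2.00-fold). The list passed without female 20-day replicate 3 (adjusted p = 0.0184). GABAergic markers (adjusted p = 0.317), potassium channels (adjusted p = 0.229), GABA and glycine receptors (adjusted p = 0.685) and synaptic vesicle genes (adjusted p = 0.685) did not pass either, but passed as lower in males with the depth term at camera's preset correlation (adjusted p = 0.0016, 0.00881, 0.00223 and 0.0256). With the depth set as a term in the model 187 genes were called, 180 higher and 7 lower, 179 of them among the 337. Of the named genes above, GBGT1 (adjusted p = 0.227), GRHPR (0.0592), RMI1 (0.0749), ATP5ME (0.227), SQLE (0.668) and the 6 lower genes (0.0708 for PAWR to 0.846 for DIS3L) then lost their call, and the log2 fold change of DIS3L went from -0.49 to -0.20. So did the astrocyte (0.0734) and growth factor (0.387) lists.

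At 50 days PVALB, SCN4B and KCNC1, genes of fast-spiking neurons, were higher in males, while markers of interneurons and of immature neurons and most of the sodium and potassium channel genes were lower. PVALB (NCBI gene 100190716) stood at 7022 ± 1030 CPM (SD, n = 5) in males and 815 ± 192 CPM (SD, n = 7) in females, 8.61-fold higher in males (adjusted p = 8.02e-10). SCN4B, the sodium channel subunit linked to resurgent current, stood at 36.1 ± 8.16 CPM (SD, n = 5) in males and 7.19 ± 2.48 CPM (SD, n = 7) in females (adjusted p = 0.000127), and KCNC1 (NCBI gene 100144433), a fast potassium channel of the Kv3 family, at 281 ± 53.2 CPM (SD, n = 5) and 152 ± 15.3 CPM (SD, n = 7) (adjusted p = 6.67e-07). SCN3B, a sodium channel subunit common in immature neurons, went the other way, with 29.6 ± 15.1 CPM (SD, n = 5) in males and 122 ± 26.1 CPM (SD, n = 7) in females (adjusted p = 9.63e-07). STMN1, a microtubule regulator of growing neurons, was 3.01-fold lower in males, at 474 ± 118 CPM (SD, n = 5) against 1429 ± 202 CPM (SD, n = 7) (adjusted p = 8.37e-09).

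In all, 5304 of 16004 genes (33.1%) differed by sex at 50 days, 2556 higher and 2748 lower in males, and 1471 of them by at least 2-fold. Z-linked genes made up 378 of the higher genes (Fisher exact test, two-sided, odds ratio 7.36, p = 9.14e-125) and 35 of the lower ones (odds ratio 0.23, p = 4.21e-25); 2003 higher and 2541 lower genes were autosomal. The homeobox gene SIX2 (NCBI gene 100218142) was read at 19.3 to 36.8 CPM in the 5 male libraries and at 0 to 1.33 CPM in the 7 female libraries (adjusted p = 2.5e-05). Next among the genes higher in males that met the naming rule were ACOT12, a Z-linked acyl-CoA thioesterase (11.8-fold), and the protocadherin PCDH12 (11.3-fold). The redox enzyme TXNRD1 (8.75-fold) and AOAH, an enzyme that inactivates lipopolysaccharide (8.48-fold), followed, and adjusted p ran from 1.26e-08 to 1.7e-05. Among genes that met the naming rule, those furthest below females were the adhesion receptor ADGRD2 (log2 fold change -4.10) and the serotonin receptor HTR1F (-2.84). The matrix protein gene NPNT (-2.58), the potassium channel KCNQ5 (-2.55), COL24A1 (-2.52) and CPNE7 (-2.39) came after them, and adjusted p ran from 1.39e-07 to 0.000141. BDNF was lower in males (log2 fold change -1.18, adjusted p = 0.00273), while the growth hormone receptor GHR (0.86, adjusted p = 0.00103) and NTRK2 (0.54, adjusted p = 6.66e-05), both Z-linked, were higher. ESR1 (log2 fold change -1.03), CYP19A1 (-0.82) and SLC17A6, the vesicular glutamate transporter of these projection neurons (0.05), were not called (adjusted p = 0.123, 0.299 and 0.784).

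**Figure D2:**
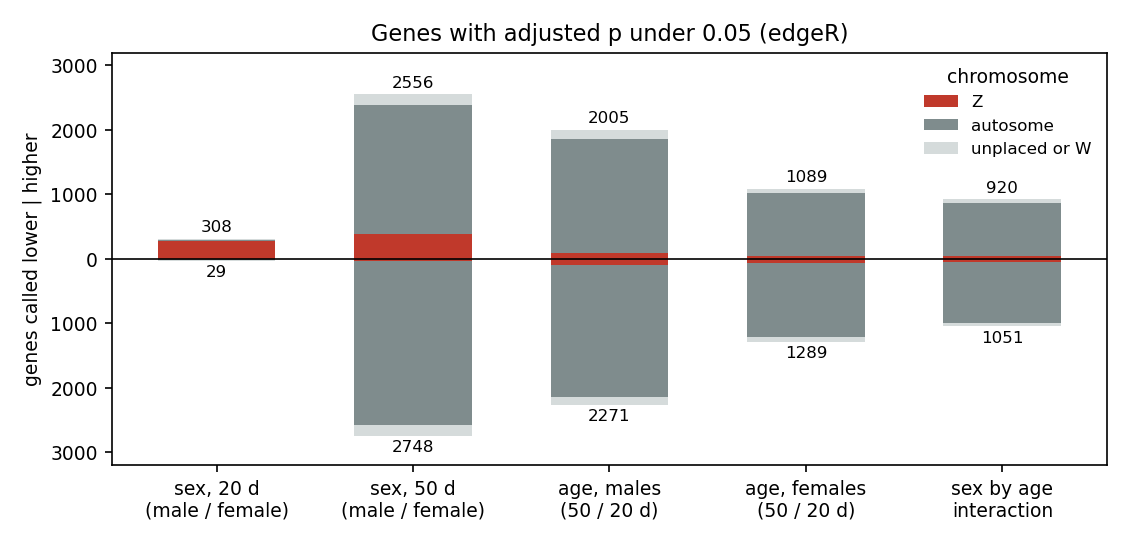
Number of genes called by edgeR (adjusted p under 0.05) in each contrast, higher above and lower below the axis, coloured by chromosome class; 281 of the 308 genes higher in males at 20 days are on Z, against 378 of 2556 at 50 days.

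Neuronal gene groups were mostly lower in males at 50 days. Of 26 GABAergic interneuron markers 21 were lower, 1 (PVALB) higher and 4 not called, or 22 lower adjusted over the list alone (camera adjusted p = 1.53e-10, and adjusted p = 0.0122 with an estimated correlation). Among them were the transcription factor DLX2 (log2 fold change -1.58) and the GABA-synthesising enzyme GAD1, at 254 ± 46.5 CPM (SD, n = 5) in males and 455 ± 48.6 CPM (SD, n = 7) in females. Immature neuron markers had 13 of 16 members lower, 2 higher and 1 not called, 14 lower adjusted over the list alone (camera adjusted p = 7.31e-07, and adjusted p = 0.0059 with an estimated correlation). They included DPYSL3, which acts in axon growth (-0.81). Axon guidance genes had 27 lower, 4 higher and 15 not called of 46, or 31 lower adjusted over the list alone (camera adjusted p = 4.79e-07, and adjusted p = 0.0344 with an estimated correlation). Members called were the ephrin receptors EPHB2 (-1.31) and EPHA6 (-1.12) and the plexin PLXNA4 (-1.30). Potassium channels were lower at 20, higher at 4 and not called at 14 of 38 members, unchanged over the list alone (camera adjusted p = 0.000336, and adjusted p = 0.1 with an estimated correlation), and within the Kv3 family KCNC4 (-1.60) and KCNC2 (-0.90) were lower where KCNC1 was higher.

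Sodium channels were lower at 7 of 9 members with 1, SCN4B, higher, the same over the list alone (camera adjusted p = 0.00324, and adjusted p = 0.16 with an estimated correlation), and SCN2A fell by 0.91 on the log2 scale. Glutamate receptors had 11 lower and 4 higher of 23, 11 and 5 over the list alone (camera adjusted p = 0.0242, and adjusted p = 0.205 with an estimated correlation; adjusted p = 0.0534 with the depth term), among the lower ones the NMDA receptor subunit GRIN2B (-1.28), typical of young synapses, and GRM5 (-1.39). For synaptic vesicle genes 15 were lower, 4 higher and 16 not called of 35, or 17 and 4 over the list alone (camera adjusted p = 0.00519, and adjusted p = 0.42 with an estimated correlation). SYN3 (-1.02) was among the lower ones, and the higher ones held VAMP1 (2.87), the vesicle SNARE of fast motor neurons, and the Z-linked complexin CPLX1 (1.07). Calcium channel and calcium-binding genes had 14 of 28 lower and 2 higher, 18 and 2 over the list alone (camera adjusted p = 7.51e-05, and adjusted p = 0.1 with an estimated correlation). GABA and glycine receptors had 11 of 17 lower (camera adjusted p = 2.66e-05, and adjusted p = 0.1 with an estimated correlation), and glutamatergic projection neuron markers 11 of 21 lower (camera adjusted p = 0.000181, and adjusted p = 0.1 with an estimated correlation).

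Energy metabolism, astrocyte and vascular lists went the other way, though none of them passed with an estimated correlation. Myelin (camera adjusted p = 0.0896, and adjusted p = 0.623 with an estimated correlation) and microglial markers (camera adjusted p = 0.391, and adjusted p = 0.756 with an estimated correlation) did not pass, though the myelin list did without male 50-day replicate 2 (0.0482) or female 50-day replicate 7 (0.0464). Of 57 oxidative phosphorylation genes 43 were higher in males and 14 not called, 49 higher adjusted over the list alone (camera adjusted p = 2.34e-16, and adjusted p = 0.16 with an estimated correlation). The ATP synthase subunit gene ATP5F1A (1.93-fold), NDUFS4 of complex I (2.75-fold) and COX7C of complex IV (2.39-fold) led the list and are Z-linked, but 4 of its tested members in all lie on Z. Glycolysis genes had 11 higher and 2 lower of 18, unchanged over the list alone (camera adjusted p = 0.00821, and adjusted p = 0.111 with an estimated correlation). Astrocyte markers were higher at 9 of 19 members, 10 over the list alone (camera adjusted p = 0.000605, and adjusted p = 0.169 with an estimated correlation). These included the bicarbonate transporter SLC4A4 (2.73-fold), SLC6A11 (1.69-fold) and the glutamate transporter SLC1A2 (1.77-fold). Endothelial and mural markers were higher at 14 and lower at 3 of 26, unchanged over the list alone (camera adjusted p = 0.000114, and adjusted p = 0.169 with an estimated correlation). They included the tight junction gene CLDN5 (1.96-fold), the Z-linked receptor TEK (3.37-fold) and the thyroid hormone transporter SLCO1C1 (1.84-fold). Immediate early genes, which report recent neuronal activity, were lower at 14 and higher at 1 of 24, unchanged over the list alone (camera adjusted p = 0.00065, and adjusted p = 0.1 with an estimated correlation). NR4A2 (-1.10) and the synaptic gene ARC (-1.37) were lower and DUSP6 (0.98) higher.

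The steroid and thyroid list split, with 8 higher and 7 lower of 33 (camera adjusted p = 0.687, and adjusted p = 0.756 with an estimated correlation). HSD17B4 (2.10-fold) and DIO2, which activates thyroid hormone (3.46-fold), were among the higher. Growth factor genes split as well, with 15 higher and 14 lower of 58, and 16 and 16 over the list alone (camera adjusted p = 0.687, and adjusted p = 0.756 with an estimated correlation). Pleiotrophin PTN (1.99-fold) and the Z-linked GDNF (4.75-fold) were higher and PDGFA (-1.11) lower. With the depth set as a term 4018 genes were called, and of the 5304 genes 100% kept their direction and 3901 their call. The shallow libraries alone gave 1956 genes and the deep ones 999. In the shallow libraries, 2 males and 6 females, BDNF (adjusted p = 0.116) was not called, and the synaptic vesicle (0.089) and glycolysis (0.0825) lists did not pass. In the deep ones, 3 males and 1 female that is taken to vary like the other groups, BDNF (adjusted p = 0.279), SCN4B (0.205), VAMP1 (0.0582), KCNC1 (0.0559), GHR (0.16), NTRK2 (0.069), KCNQ5 (0.138), TXNRD1 (0.0511), AOAH (0.13), ADGRD2 (0.245), NPNT (0.0879), CPNE7 (0.0816), CPLX1 (0.138), SLC1A2 (0.0734), CLDN5 (0.091) and SLCO1C1 (0.0725) were not called, and the glutamate receptor list (0.133) did not pass.

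**Figure D3:**
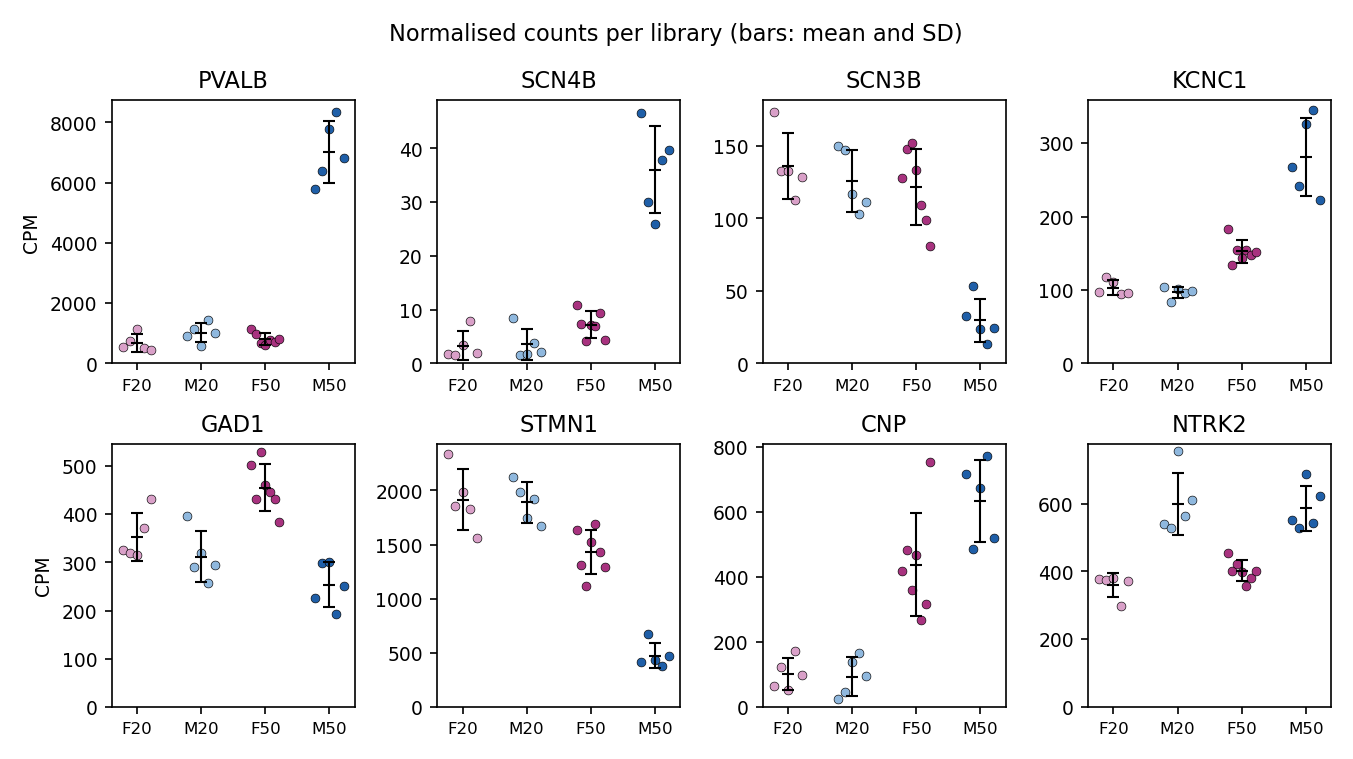
Normalised counts (CPM) of 8 genes in each library, F20 and M20 for female and male at 20 days and F50 and M50 at 50 days, with bars for the group mean and SD; PVALB, SCN4B and KCNC1 are highest, and SCN3B and STMN1 lowest, in the male libraries at 50 days.

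Between 20 and 50 days, the male nucleus gained myelin and glycolysis transcripts and lost transcripts of growing neurons, but the myelin list did not pass with an estimated correlation (adjusted p = 0.191). CNP, an enzyme gene of myelinating cells, stood at 93.0 ± 59.7 CPM (SD, n = 5) at 20 days and 633 ± 125 CPM (SD, n = 5) at 50 days (adjusted p = 2.81e-05). STMN1 fell from 1889 ± 186 CPM (SD, n = 5) to 474 ± 118 CPM (SD, n = 5) (adjusted p = 1.89e-09), and the axon growth gene GAP43 fell by 2.09 on the log2 scale (adjusted p = 9.52e-09). PVALB rose 6.92-fold (adjusted p = 5.13e-08), KCNC1 2.90-fold (adjusted p = 2.69e-09) and SCN4B 10.1-fold (adjusted p = 1.99e-05), while SCN3B fell by 2.09 on the log2 scale (adjusted p = 2.14e-06).

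Age changed 4276 genes in males (26.7%), 2005 higher and 2271 lower at 50 days. SIX2 had 0 counts in the 5 male libraries at 20 days and was at least 1059-fold higher at 50 days, against a floor of 3 counts over the group that covers counting error only. Large rises were seen for APOH, a plasma glycoprotein gene (122-fold), the oligodendrocyte factor NKX6-2 (27.7-fold), TMEM278 (26.1-fold), ANLN, an actin-binding gene found in myelin (17.4-fold), and the fast calcium sensor SYT2 (17.2-fold), with adjusted p from 5.13e-08 to 1e-04. Large falls were seen for the melanocortin receptor MC5R (log2 fold change -5.98), the adrenergic receptor ADRA2A (-3.85), the corticotropin-releasing hormone receptor CRHR1 (-3.78), TRAF5 (-3.33), KCNQ5 (-3.19) and the embryonic globin gene HBE1 (-3.08), with adjusted p from 1.51e-09 to 0.00125. BDNF fell (log2 fold change -2.20, adjusted p = 1.47e-05) and GHR rose (0.90, adjusted p = 0.00201). ESR1, CYP19A1, NTRK2, SLC17A6 and GAD1 were not called, with adjusted p from 0.0935 for GAD1 to 0.93 for ESR1; GAD1 passed without male 20-day replicate 4 (0.0489) or male 50-day replicate 3 (0.0498).

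Immature neuron markers fell at 15 of 16 members with 1 not called, the same over the list alone (camera adjusted p = 2.1e-13, and adjusted p = 0.000153 with an estimated correlation). Among them were DPYSL3 (log2 fold change -1.87) and SOX11 (-1.70). Axon guidance genes fell at 26 and rose at 2 of 46, 27 and 5 over the list alone (camera adjusted p = 3.33e-06, and adjusted p = 0.0734 with an estimated correlation). Called members were EPHB2 (-1.65), PLXNA2 (-1.42) and PLXNA4 (-1.60). Myelin markers rose at 18 and fell at 1 of 24, 19 and 1 over the list alone (camera adjusted p = 8.18e-10, and adjusted p = 0.191 with an estimated correlation). CNP rose 6.80-fold, and HAPLN2 had 0 counts at 20 days and was at least 279.7-fold higher at 50 days against the floor of 3 counts. Glycolysis genes rose at 14 and fell at 1 of 18, 15 and 2 over the list alone (camera adjusted p = 1.82e-05, and adjusted p = 0.025 with an estimated correlation). Among them were ENO1 (1.51-fold), PKM (1.68-fold) and the lactate transporter SLC16A1 (2.18-fold). Oxidative phosphorylation genes rose at 30 of 57, 35 over the list alone (camera adjusted p = 1.39e-09, and adjusted p = 0.34 with an estimated correlation). Members called were SDHA (1.67-fold), SDHD (1.66-fold) and NDUFS8 (1.42-fold). Astrocyte markers rose at 10 of 19, 11 over the list alone with 1 lower (camera adjusted p = 0.00206, and adjusted p = 0.264 with an estimated correlation). SLC4A4 rose 1.85-fold. Endothelial and mural markers rose at 11 of 26 (camera adjusted p = 9.09e-05, and adjusted p = 0.264 with an estimated correlation). CLDN5 rose 1.60-fold. Synaptic vesicle genes split evenly, with 7 higher and 7 lower of 35, 8 and 10 over the list alone (camera adjusted p = 0.897, and adjusted p = 0.951 with an estimated correlation). CPLX1 rose (1.58) and SYN3 (-1.46) and SYT4 (-1.36) fell. GABAergic markers, in contrast to females, fell at 11 and rose at 1 of 26, 12 and 1 over the list alone (camera adjusted p = 0.00229, and adjusted p = 0.264 with an estimated correlation). Sodium channels fell at 5 and rose at 1 of 9, 6 and 1 over the list alone (camera adjusted p = 0.017, and adjusted p = 0.274 with an estimated correlation). Calcium channel and calcium-binding genes fell at 13 and rose at 3 of 28, 14 and 3 over the list alone (camera adjusted p = 0.00472, and adjusted p = 0.264 with an estimated correlation). GABA and glycine receptors fell at 7 and rose at 1 of 17, 8 and 1 over the list alone (camera adjusted p = 0.028, and adjusted p = 0.388 with an estimated correlation; 0.0644 without male 50-day replicate 1). Projection neuron markers fell at 7 of 21, 7 over the list alone (camera adjusted p = 0.00578, and adjusted p = 0.264 with an estimated correlation). Immediate early genes fell at 8 and rose at 2 of 24, 9 and 2 over the list alone (camera adjusted p = 0.0206, and adjusted p = 0.264 with an estimated correlation). Ribosomal protein genes fell at 5 and rose at 1 of 62, with only 1 higher over the list alone (camera adjusted p = 0.0375, and adjusted p = 0.751 with an estimated correlation). The ribosomal list lost its call in 6 of the 22 fits without 1 library (adjusted p up to 0.117). Fitted with the depth set, 2712 genes were called, 2635 of them among the 4276, and HBE1 lost its call (adjusted p = 0.0655), as did the GABA and glycine receptor (0.162) and ribosomal (0.278) lists. The shallow libraries alone, 5 at 20 days and 2 at 50 days, gave 1546 genes, with NDUFS8 not called (adjusted p = 0.065) and the GABA and glycine receptor (0.397), ribosomal (0.0567) and microglial (0.0536) lists not passing.

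In females the same interval brought myelin markers and 11 of 26 GABAergic markers up and immature neuron markers down, but the myelin and GABAergic lists did not pass with an estimated correlation (adjusted p = 0.143 and 0.143). CNP stood at 102 ± 48.3 CPM (SD, n = 5) at 20 days and 437 ± 159 CPM (SD, n = 7) at 50 days, and GAD1 at 352 ± 49.6 CPM (SD, n = 5) and 455 ± 48.6 CPM (SD, n = 7) (adjusted p = 0.0393 for GAD1). PROX1, a transcription factor of interneurons, rose 2.27-fold (adjusted p = 1.57e-05), DLX1 1.84-fold (adjusted p = 0.000313) and SOX6 1.44-fold (adjusted p = 0.00385). Adding the depth term took the log2 fold change from 0.37 to 0.13 for GAD1 (adjusted p = 0.695), from 0.88 to 0.53 for DLX1 (0.103) and from 0.52 to 0.49 for SOX6 (0.097), and the 3 lost their call. DPYSL3 fell by 1.19 on the log2 scale (adjusted p = 4.29e-09) and the Z-linked growth gene NREP by 1.23 (adjusted p = 3.48e-07).

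Age changed 2378 genes in females (14.9%), 1089 higher and 1289 lower at 50 days. The largest rises are given among called genes with a symbol, a mean of at least 5 CPM and no overlap between the groups. They were those of APOH (123-fold), TMEM278 (19.1-fold), NKX6-2 (18.3-fold) and the myelin gene ERMN (9.14-fold). The Z-linked lysophosphatidic acid receptor LPAR1 (9.12-fold) and the tight junction gene of myelin CLDN11 (7.63-fold) came next, and adjusted p ran from 9.09e-07 to 0.0222. By the same limits the largest falls were those of HBE1 (log2 fold change -6.38), MC5R (-4.42) and VXN (-2.00). PCDH12 (-1.99), PRSS12 (-1.97) and the steroid reductase AKR1D1 (-1.91) came next, and the adjusted p of these genes ran from 3.1e-06 to 0.00446. KCNC1 rose by a log2 fold change of 0.56 (adjusted p = 0.00075). PVALB, SCN3B, ESR1, CYP19A1, GHR, NTRK2, BDNF and SLC17A6 were not called (adjusted p from 0.103 for SLC17A6 to 0.682 for SCN3B), although BDNF passed without female 50-day replicate 1 (0.0323). SCN4B (log2 fold change 1.12, adjusted p = 0.0784) was not called with edgeR and passed with DESeq2 (0.0328), with limma voom (0.0239), without female 20-day replicate 4 (0.00743) and without male 20-day replicate 1 (0.0427). CLDN11 lost its call without female 20-day replicate 5 (adjusted p = 0.0555), and GAD1 without any of 7 libraries (up to 0.0963) or with the counts of female 50-day replicates 5 and 6 summed (0.0504).

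Myelin markers rose at 15 of 24 members, 16 over the list alone (camera adjusted p = 9.05e-12, and adjusted p = 0.143 with an estimated correlation). They included HAPLN2, at 0.0154 to 0.217 CPM in the 20-day and 1.01 to 9.2 CPM in the 50-day libraries, and ST18 (4.92-fold). GABAergic markers rose at 11 of 26, 13 over the list alone with 1 lower (camera adjusted p = 3.28e-06, and adjusted p = 0.143 with an estimated correlation). Immature neuron markers fell at 8 of 16, 9 over the list alone (camera adjusted p = 3.08e-05, and adjusted p = 0.0412 with an estimated correlation), SOX11 among them (-0.62). Microglial markers rose at 5 of 22, 8 over the list alone (camera adjusted p = 0.000806, and adjusted p = 0.364 with an estimated correlation). Called members were CD74 (3.40-fold), C1QC (2.02-fold), GPR34 (1.69-fold) and others. Cell cycle genes fell at 7 and rose at 1 of 29, 8 and 2 over the list alone (camera adjusted p = 0.000299, and adjusted p = 0.315 with an estimated correlation). Among them were CDCA3 (-2.08) and the mitotic kinase CDK1 (-1.53; adjusted p = 0.057 without female 20-day replicate 3). Cytosolic ribosomal protein genes fell at 8 of 62, the same over the list alone (camera adjusted p = 2.19e-07, and adjusted p = 0.549 with an estimated correlation). Members called were RPL13 (-0.46), RPL8 (-0.46) and RPS18 (-0.63). Cholesterol synthesis genes fell at 7 of 20, the same over the list alone (camera adjusted p = 0.00378, and adjusted p = 0.315 with an estimated correlation). These included HMGCS1 (-0.71), HSD17B7 (-0.62) and ACAT2 (-0.47). Glutamate receptors rose at 4 and fell at 1 of 23, 4 and 1 over the list alone (camera adjusted p = 0.0371, and adjusted p = 0.315 with an estimated correlation; 0.0685 without female 20-day replicate 3, 0.057 without replicate 4 and 0.0945 without female 50-day replicate 3). Synaptic vesicle genes rose at 10 and fell at 4 of 35, 13 and 4 over the list alone (camera adjusted p = 0.00519, and adjusted p = 0.549 with an estimated correlation). Cell death genes did not pass as a list (camera adjusted p = 0.0592, and adjusted p = 0.315 with an estimated correlation), save without any 1 of 5 libraries (down to 0.0171), but 7 of 36 fell, 9 over the list alone with 1 higher, among them SARM1 (-0.98) and APAF1 (-0.87). All 5 libraries at 20 days and 1 of 7 at 50 days were deep. A depth term left 744 genes called, 708 of them among the 2378, and the deep libraries alone, with 1 at 50 days, gave 21. That single library is taken to vary like the other groups. With the depth term CLDN11 (0.149), AKR1D1 (0.593), C1QC (0.166), GPR34 (0.427), CDCA3 (0.0727), CDK1 (0.249), RPL8 (0.119), RPS18 (0.104) and ACAT2 (0.0854) lost their call as well. So did the cell cycle (0.195), cholesterol (0.346), glutamate receptor (0.587) and synaptic vesicle (0.397) lists. The log2 fold change went to -0.74 for AKR1D1 and from 0.76 to 0.40 for GPR34.

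The age changes of the sexes overlapped beyond what independent lists give. Of the genes that rose in males (2005) and in females (1089), 429 rose in both, against 136.4 for independent lists of those lengths, and 601 fell in both against 182.9. Opposite changes were fewer, with 79 rising in males and falling in females (161.5 for independent lists) and 62 the reverse (154.5). Under the depth term 150 rose in both, 233 fell in both and 22 changed in opposite directions. APOH, TMEM278, NKX6-2, GHR and the falling MC5R, HBE1, SOX11 and DPYSL3 show the range, since GHR was called in males alone (interaction adjusted p = 0.093) and the others in both. Across genes the log2 fold changes correlated with r = 0.269 (Spearman 0.244), where simulated unchanged groups gave a mean of -0.00106; genes are not independent replicates.

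**Figure D4:**
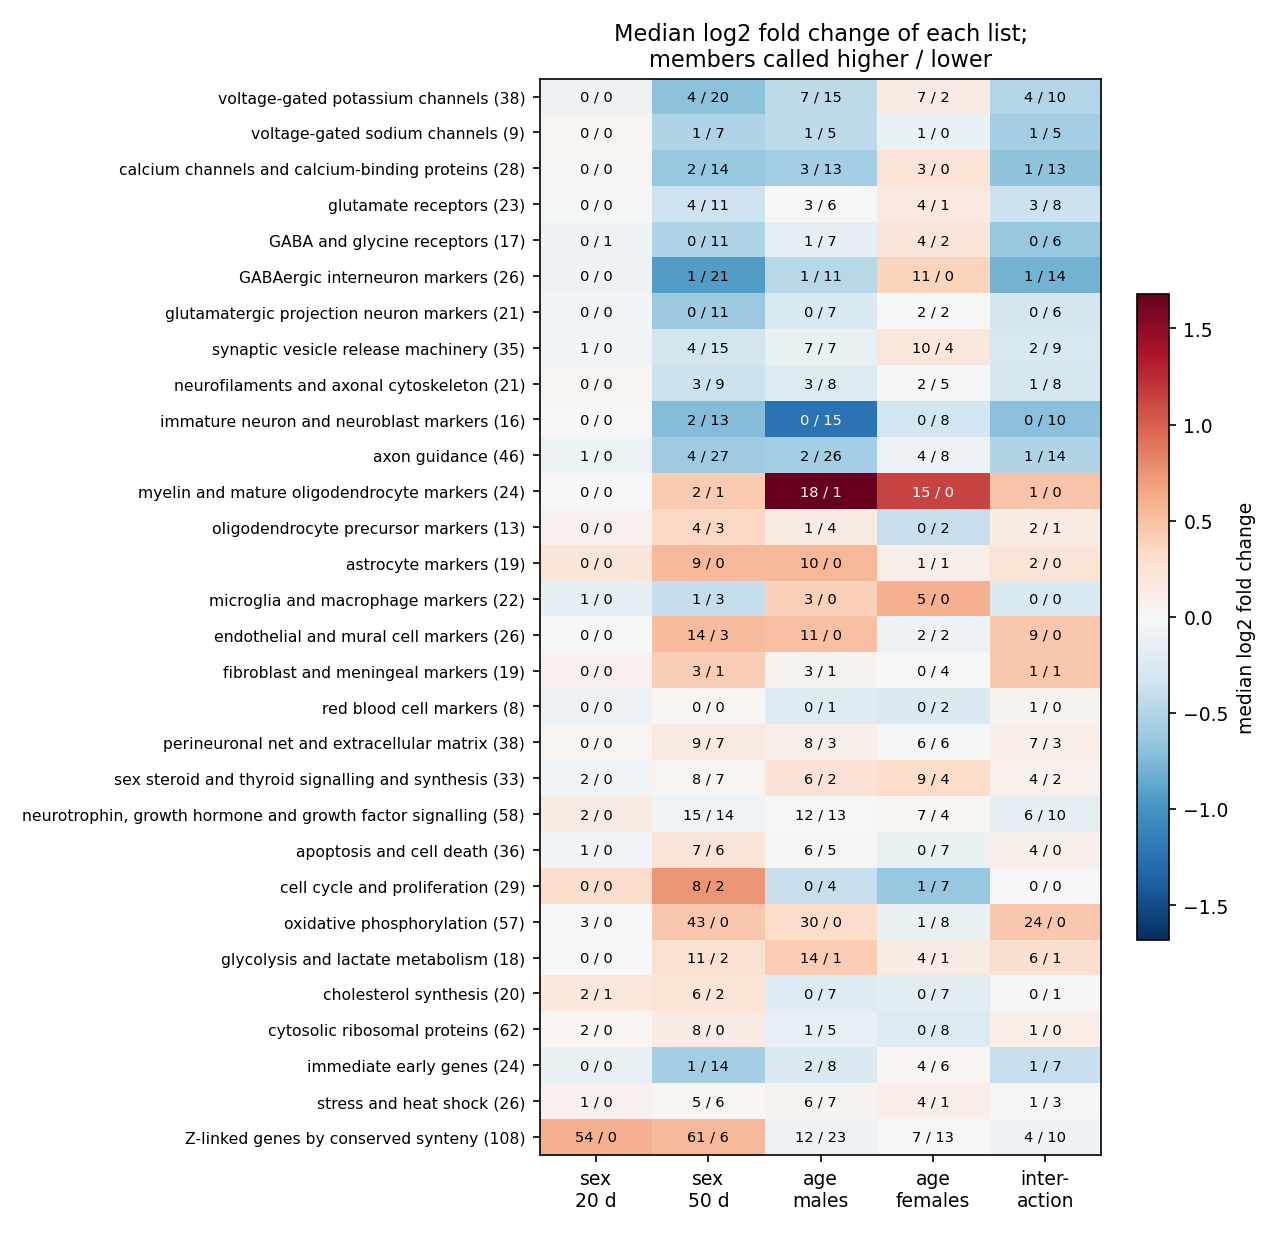
Median log2 fold change (colour) of the tested members of each fixed list in the 5 contrasts, with the number of members called higher / lower; the number in brackets is the members tested. The immature neuron list has 15 of 16 members lower with age in males, and the GABAergic list 21 of 26 lower in males at 50 days and 11 of 26 higher with age in females.

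The interaction tests whether the sex difference changed between the ages, and it did so for PVALB, KCNC1 and SCN4B and for markers of interneurons and of immature neurons. The male-to-female difference grew with age by a log2 fold change of 2.53 (SE 0.32, adjusted p = 6.78e-05) for PVALB, 0.97 (0.15, adjusted p = 0.000243) for KCNC1 and 2.22 (0.61, adjusted p = 0.0196) for SCN4B, which lost its call without female 20-day replicate 4 (0.0563). It fell for SCN3B (-1.93), KCNC4 (-1.62), STMN1 (-1.57), BDNF (-1.58) and GAD1 (-0.67), with adjusted p from 4.38e-05 for STMN1 to 0.0147 for GAD1. PVALB and STMN1 kept their call with the depth term, while KCNC1 (log2 fold change 1.03, adjusted p = 0.055), SCN4B (1.44, adjusted p = 0.565), SCN3B (-1.15, adjusted p = 0.301), KCNC4 (-1.12, adjusted p = 0.088), BDNF (-1.26, adjusted p = 0.454) and GAD1 (-0.27, adjusted p = 0.703) lost it. ESR1, CYP19A1, NTRK2 and SLC17A6 were not called, with adjusted p from 0.389 for NTRK2 to 0.977 for SLC17A6. GHR (log2 fold change 0.72, adjusted p = 0.093) was not called either, but passed with DESeq2 (0.0493), with limma voom (0.0355), without female 20-day replicate 2 (0.0472) and without female 50-day replicate 7 (0.0385).

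In all, 1971 genes (12.3%) were called, 920 with a rise and 1051 with a fall of the male-to-female ratio. Among genes with the largest rise was TPH1, the rate-limiting enzyme of serotonin synthesis (adjusted p = 0.000549, and 0.0847 with limma voom). It was read at 30.43 to 60.46 CPM in 4 of the 5 male 50-day libraries, at 1.401 CPM in replicate 2 and at 0.1245 to 3.033 CPM elsewhere. SIX2 was called (adjusted p = 0.0272), but not without female 20-day replicate 4 (0.482), since the 20-day groups held 12 and 0 counts. LAMTOR1 (adjusted p = 0.00411) was near 60 CPM in female 20-day replicates 4 (61.4) and 5 (55.81) and male 50-day replicates 4 (61.48) and 5 (58.23) and at 2.416 to 6.327 CPM elsewhere. TMEM269 (adjusted p = 0.0234, but 0.0802 without female 20-day replicate 3 and 0.0571 without male 50-day replicate 5) also rested on single libraries. So did VIPR1 (adjusted p = 0.0227, but 0.0562 without female 20-day replicate 5 and 0.0796 without male 50-day replicate 4) and HBE1 (adjusted p = 0.0185, but 0.0671 without male 50-day replicate 1). Among the falls, UCN3, a neuropeptide of the stress system, was at 136.6 and 170.8 CPM in male 20-day replicates 4 and 5, at 47.16 to 122.9 CPM in female 50-day replicates 5 to 7 and at no more than 0.2809 CPM elsewhere (adjusted p = 0.000764). ADRA2A (log2 fold change -4.16), KCNQ5 (-3.17), ADGRD2 (-3.44), CPNE7 (-2.87) and PALM (-2.69; adjusted p = 0.0518 without male 20-day replicate 2) fell with adjusted p from 0.000723 to 0.0256. With limma voom LAMTOR1 (0.13), TMEM269 (0.445), VIPR1 (0.295), HBE1 (0.299), UCN3 (0.302), ADGRD2 (0.0672) and PALM (0.0603) were not called.

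GABAergic markers fell in males relative to females at 14 of 26 members and rose at 1, or 15 and 1 over the list alone (camera adjusted p = 9.79e-10, and adjusted p = 0.024 with an estimated correlation). Called members were PROX1 (-1.34) and the vesicular GABA transporter SLC32A1 (-0.78). Immature neuron markers fell at 10 of 16, 13 over the list alone (camera adjusted p = 7.07e-08, and adjusted p = 0.00479 with an estimated correlation). Among them were DPYSL3 (-0.67) and SOX11 (-1.08). Potassium channels fell at 10 and rose at 4 of 38, 12 and 6 over the list alone (camera adjusted p = 0.00387, and adjusted p = 0.156 with an estimated correlation). Calcium channel and calcium-binding genes fell at 13 and rose at 1 of 28, 14 and 2 over the list alone (camera adjusted p = 2.38e-05, and adjusted p = 0.119 with an estimated correlation). Glutamate receptors fell at 8 and rose at 3 of 23, 8 and 3 over the list alone (camera adjusted p = 0.0238, and adjusted p = 0.229 with an estimated correlation; 0.0591 without female 50-day replicate 3). GABA and glycine receptors fell at 6 of 17, 10 over the list alone (camera adjusted p = 5.5e-05, and adjusted p = 0.156 with an estimated correlation). Projection neuron markers fell at 6 of 21, 8 over the list alone (camera adjusted p = 0.00261, and adjusted p = 0.156 with an estimated correlation). Synaptic vesicle genes fell at 9 and rose at 2 of 35, 12 and 2 over the list alone (camera adjusted p = 0.0218, and adjusted p = 0.565 with an estimated correlation; 0.0666 without male 20-day replicate 1, 0.0591 without female 50-day replicate 3 and 0.0823 without male 50-day replicate 5). Neurofilament and axonal cytoskeleton genes fell at 8 and rose at 1 of 21, 10 and 4 over the list alone. That list had a camera adjusted p of 0.00387, and an adjusted p of 0.37 with an estimated correlation. Astrocyte markers rose at 2 of 19, 2 over the list alone (camera adjusted p = 0.0147, and adjusted p = 0.37 with an estimated correlation; 0.0813 without male 20-day replicate 1). Glycolysis genes rose at 6 and fell at 1 of 18, 6 and 1 over the list alone (camera adjusted p = 0.00295, and adjusted p = 0.119 with an estimated correlation). Sodium channels fell at 5 and rose at 1 of 9, 5 and 1 over the list alone (camera adjusted p = 0.00295, and adjusted p = 0.156 with an estimated correlation). Axon guidance genes fell at 14 of 46, 19 over the list alone (camera adjusted p = 6.07e-06, and adjusted p = 0.0854 with an estimated correlation). Oxidative phosphorylation genes rose at 24 of 57, 36 over the list alone (camera adjusted p = 2.33e-15, and adjusted p = 0.162 with an estimated correlation). Members called were NDUFA10 (0.57), SDHD (0.76) and NDUFS3 (0.85). Endothelial and mural markers rose at 9 of 26, 11 over the list alone (camera adjusted p = 3.16e-05, and adjusted p = 0.156 with an estimated correlation). They included CLDN5 (1.03), EGFL7 (1.42) and SLCO1C1 (0.76). Immediate early genes fell at 7 and rose at 1 of 24, 10 and 1 over the list alone (camera adjusted p = 0.00387, and adjusted p = 0.156 with an estimated correlation). Among them were NR4A2 (-0.77), KLF6 (-1.18) and ARC (-1.34). With the depth term 72 genes were called (38 and 34), 71 of them among the 1971, of which 99.7% kept their direction. Of 34 named genes with a call 3 kept it, namely PVALB, STMN1 and UCN3, and 31 lost it. Among them the log2 fold changes of LAMTOR1 (5.28 to 1.24), TMEM269 (4.22 to 1.97), VIPR1 (3.76 to 1.35), CPNE7 (-2.87 to -1.23) and EGFL7 (1.42 to 0.94) also shrank by over 1.5 times. Of 16 list calls 5 were lost, those of potassium channels (0.244), glutamate receptors (0.478), GABA and glycine receptors (0.176), synaptic vesicle genes (0.785) and astrocyte markers (0.0542).

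Many of the genes that differed by sex at 50 days had changed with age in males. Of the 2556 genes higher in males at 50 days, 1200 (46.9%) had risen with age in males and 447 (17.5%) had fallen with age in females, and 988 had been called in neither. Of the 2748 lower genes, 1443 (52.5%) had fallen in males, 391 (14.2%) had risen in females and 974 were called in neither. When depth was a term, 1953 genes were called higher and 2065 lower in males at 50 days. Of those 1953 genes 735 had risen in males and 106 fallen in females. Of the 2065 genes 902 had fallen in males and 82 risen in females. PVALB, KCNC1 and the falling SCN3B changed with age in males, PCDH12 fell with age in females, and PROX1 and DLX1 rose with age in females. The contrasts share the 50-day libraries. Independent lists would share 320.2 and 389.9 genes with the male age change and 205.9 and 187.0 with the female one. When the male 50-day libraries were split so that the contrasts shared none, the median over 20 splits was 667.5 shared higher genes against 158.9 for independent lists, and 763 lower against 170.9; for females it was 207 against 100.8 and 180 against 93.28. Across genes the sex difference at 50 days and the age change in males had a covariance of 0.408 (r = 0.672), against 0.0799 (r = 0.532) in the simulation, and for the age change in females the covariance was -0.138 (r = -0.301) against -0.0577 (r = -0.426). Of the 378 Z-linked genes higher at 50 days, 253 were already higher at 20 days, and 83 rose with age in males.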

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

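The comparison of 100 splits, the test with equal numbers of libraries and the first test of the paired brains were set before their results were seen, and the tests of depth and the second test of that pair were chosen after.

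Of 52 groups of values checked for a library far from the others 4 held one, where about 1 in 20 is found by chance. Female 50-day replicate 6 had total counts of 51.6 M against 17.6 M to 21.6 M. KCNC1 was at 183 CPM in female 50-day replicate 1 against 134 to 155 CPM in the others. NTRK2 was at 298 CPM in female 20-day replicate 4 against 371 to 381 CPM, and SIX2 at 0.199 CPM in that library against 0 to 0.0198 CPM.

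Of the genes named here and in the report, 80 had a sex difference that changed with age by the interaction test, given here as log2 fold changes. Channels and receptors were SCN4B 2.22, KCNC1 0.97, SCN3B -1.93, SCN2A -0.83, KCNC4 -1.62, KCNC2 -0.80, KCNQ5 -3.17, GRIN2B -1.41, GRM5 -1.44, HTR1F -2.40, ADRA2A -4.16, CRHR1 -1.93, ADGRD2 -3.44 and VIPR1 3.76. Interneuron and synapse genes were PVALB 2.53, GAD1 -0.67, SLC32A1 -0.78, PROX1 -1.34, DLX1 -1.20, DLX2 -1.15, SOX6 -0.80, VAMP1 2.90, CPLX1 0.97, SYN3 -1.10 and SYT4 -0.92. Growth and guidance genes were STMN1 -1.57, GAP43 -0.89, DPYSL3 -0.67, SOX11 -1.08, EPHB2 -1.05, EPHA6 -1.35, PLXNA2 -1.01, PLXNA4 -1.25, BDNF -1.58, PTN 0.83, PDGFA -0.79 and GDNF 1.53. Metabolic genes were ATP5F1A 0.26, COX7C 0.81, SDHA 0.48, SDHD 0.76, NDUFS8 0.59, NDUFS3 0.85, NDUFA10 0.57, UQCRFS1 0.46, ENO1 0.54, PKM 0.44, SLC16A1 0.72, ACOT12 2.67 and DIO2 1.48.

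Vascular, glial and matrix genes were CLDN5 1.03, EGFL7 1.42, TEK 1.31, SLCO1C1 0.76, COL4A1 1.70, COL24A1 -1.75, NPNT -2.40, PCDH12 2.77, SLC4A4 1.11 and SLC6A11 0.61. Activity genes were NR4A2 -0.77, ARC -1.34, DUSP6 0.72, KLF6 -1.18 and EGR1 -1.66. The others were LAMTOR1 5.28, TPH1 4.95, TMEM269 4.22, PALM -2.69, CPNE7 -2.87, AOAH 2.75, TRAF5 -1.49, HBE1 3.30, GBGT1 -1.82, PAWR 1.07, FILIP1L 0.65 and RPS28 1.23. For SIX2, UCN3 and HAPLN2 the fit gave 10.21, -22.92 and 6.02, but with groups at or near 0 counts these are neither estimates nor bounds of the fold.

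Many genes differed by sex at 50 days (5304) and few at 20 days (337). With 5 of the 7 female libraries the count at 50 days was 4350 to 5271 over 21 choices, so unequal numbers do not explain the gap. In the shallow libraries alone, 2 males and 6 females, 1956 genes differed by sex at 50 days, against at most 12 in the 27 other placements of the male labels, so a depth difference does not explain the many calls at 50 days. That 99.8% of the 5298 genes tested there kept their direction decides nothing, since they were chosen in a fit that held the same libraries. Of 100 splits of the libraries the real one was the only one to call as many genes, 1 of 100 in each of the 5 contrasts. The highest other counts were 6 for sex at 20 days, 1684 for sex at 50 days and 969 and 154 for age in males and females. For the interaction it was 161, but those splits exchanged sex labels within each age. They removed the sex difference as well, so they cannot decide whether the interaction alone exceeds chance. At 20 days no other split parted the depth sets as the real one did, so the splits do not part sex from depth. At 20 days sex and depth coincide, so a depth effect could hide sex differences of opposite sign there. With the depth term, which is set by the 50-day libraries alone, 187 genes were called, 179 of them among the 337, and the potassium channel, GABA and glycine receptor, GABAergic and synaptic vesicle lists passed as lower in males at camera's preset correlation (adjusted p = 0.00881, 0.00223, 0.0016 and 0.0256).

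The interaction could carry a share of depth, since the groups differ in it. With the depth set as a term the median fold of the called genes was 0.883 of itself, while the count fell from 1971 to 72. That test cannot tell the explanations apart. In simulated counts with no depth effect the same term lowered recovery of 2-fold interactions from 46% to 4%, and on the real data it raised the standard errors 1.56-fold, so calls would be lost through the overlap of depth with the groups even with no depth effect.

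Female 50-day replicates 5 and 6, whose brain ids share a number, may be 1 bird. Over genes that are on in some libraries and off in others by a gap of 3 log2, found without the pair, they shared the state at 100% of 2 genes, but so did 99 of 230 other pairs, which cannot tell. A limit on the number of genes and a smaller gap were then chosen after that result. With a gap of 1.5 log2 the pair shared the state at 100% of 13 genes, against 92.3% in the closest other pair and 84.6% in the closest other female 50-day pair and in female 20-day replicates 4 and 5, which correlate nearly as highly. This is consistent with 1 bird but does not prove it. With their counts summed, 5001 genes differed by sex at 50 days.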

How the results depend on the processing

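The depth term, the fits of 1 depth set, thinning, robust dispersions, the Z score from the synteny list and the overlaps without each library were chosen after the data were seen, and the other settings before. No named gene changed sign with a call on either side, and no list its camera direction, but the median fold of the cell cycle list at 50 days went from 0.736 to -0.135 in the shallow libraries, and the medians of GABA and glycine receptors for age in males (-0.149 to 0.000421, shallow libraries) and of Z-linked genes by synteny for age in females (0.00185 to -0.077, deep libraries) changed sign as well. DESeq2 (487, 5743, 4664, 3031 and 2543 genes for sex at 20 days, sex at 50 days, age in males, age in females and the interaction) and voom (442, 5419, 4414, 2867 and 2133) stayed within 1.5 times the edgeR counts, as did the filters, the other scaling, thinning, robust dispersions and the summed pair. A fold of at least 2 left 98, 1471, 1335, 512 and 751 genes, and an adjusted p under 0.01 left 3500, 2665, 1109 and 755 for the last 4, by construction. The depth term left 187, 2712, 744 and 72 for sex at 20 days, age in males, age in females and the interaction. The shallow libraries alone gave 1956 for sex at 50 days and 1546 for age in males, and the deep ones 999 for sex at 50 days and 21 for age in females, with fewer libraries. Genes with age changes in both sexes numbered 215 higher, 315 lower and 31 opposite at an adjusted p under 0.01, and 150, 233 and 22 with the depth term. These settings called 1751 and 1953 genes higher and 1749 and 2065 lower in males at 50 days. Of the higher ones 687 and 735 had risen in males and 164 and 106 fallen in females. Of the lower ones 862 and 902 had fallen in males and 127 and 82 risen in females. Under the depth term the median standard error of the called genes rose 1.5-fold, 1.21-fold, 1.44-fold and 1.56-fold for sex at 20 days, age in males, age in females and the interaction, and their median fold was 0.999, 0.948, 1.03 and 0.883 of itself. Leaving out each library gave 287 to 351, 4477 to 5350, 3639 to 4366, 1746 to 2421 and 1506 to 2131 genes, Z score differences of 0.602 to 0.621 and 0.593 to 0.619, and opposite age changes of 86 (without female 20-day replicate 4) to 153. Of 188 named gene calls 174 held in each such fit that tested the gene, and of 67 list calls 53. Among the 174 is UCN3 for the interaction, which was tested in only 19 of the 22 fits. The replicate numbers do not pair the libraries: of 30 pairs with the same number 3 had correlated deviations (r over 0.1) and 4 libraries matched their own number best. The replicate block gave 314, 4765, 4051, 1716 and 1764 genes, and of 220 named results 8 lost their call. Of 67 list calls 57 were lost with an estimated correlation and 11 with fry, which added 16. The self-test recovered 7% of 1.5-fold interactions.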

Other observations

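The test of fold size across Z-linked genes was chosen after the result was seen.

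Cytosolic ribosomal protein genes were higher in males at 50 days at 8 of 62 members, 5 over the list alone (camera adjusted p = 0.00308, and adjusted p = 0.627 with an estimated correlation), among them RPS28 (log2 fold change 1.43). Cell cycle genes were higher at 8 and lower at 2 of 29, the same over the list alone (camera adjusted p = 0.0271, and adjusted p = 0.42 with an estimated correlation; adjusted p = 0.113 without male 50-day replicate 5 and 0.0715 without replicate 4), with UBE2C (2.11) and CDK1 (1.57), both markers of dividing cells. Cholesterol synthesis genes were higher at 6 and lower at 2 of 20, 8 and 2 over the list alone (camera adjusted p = 0.0477, and adjusted p = 0.42 with an estimated correlation), and this list lost its call in 7 of the 22 fits without 1 library. With the depth term the cell cycle (0.139) and cholesterol (0.162) lists lost their call at 50 days, and the median fold of the cell cycle list changed sign in the shallow libraries. In the shallow libraries both lists (0.745 and 0.0991) and CDK1 (0.201) were not called, nor in the deep ones CDK1 (0.186), UBE2C (0.535) and the cholesterol list (0.628). In males these genes fell with age at 7 of 20, 8 over the list alone (camera adjusted p = 0.0249, and adjusted p = 0.388 with an estimated correlation; adjusted p = 0.0512 without male 20-day replicate 4). Microglial genes rose with age in males at 3 of 22 (camera adjusted p = 0.0294, and adjusted p = 0.468 with an estimated correlation), with CD74, an immune chaperone (1.52), and the list lost its call in 3 of 22 such fits. Oxidative phosphorylation genes fell with age in females at 8 and rose at 1 of 57, the same over the list alone (camera adjusted p = 0.00459, and adjusted p = 0.72 with an estimated correlation), with UQCRFS1 (-0.34), and lost the call in 2 such fits.

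Neurofilament and axonal cytoskeleton genes fell with age in males at 8 and rose at 3 of 21 (camera adjusted p = 0.00389, and adjusted p = 0.384 with an estimated correlation). In the list of perineuronal net and extracellular matrix genes the collagen gene COL4A1 was higher in males at 50 days (1.72). Of the 38 members 9 were higher and 7 lower. The list did not pass (camera adjusted p = 0.159, and adjusted p = 0.411 with an estimated correlation). Nor did stress genes (5 and 6 of 26; camera adjusted p = 0.822, and adjusted p = 0.928 with an estimated correlation) and oligodendrocyte precursor markers (4 and 3 of 13; camera adjusted p = 0.357, and adjusted p = 0.464 with an estimated correlation) pass. With age in females the stress genes CRYAB (2.14) and HMOX1 (1.09) and the activity gene EGR1 (1.63) rose, but their lists did not pass. Stress genes had 4 higher and 1 lower of 26 (camera adjusted p = 0.149, and adjusted p = 0.66 with an estimated correlation). Immediate early genes had 4 higher and 6 lower of 24 (camera adjusted p = 0.982, and adjusted p = 0.988 with an estimated correlation). Between the sexes at 50 days fibroblast and meningeal markers had 3 higher and 1 lower of 19 (camera adjusted p = 0.163, and adjusted p = 0.42 with an estimated correlation). Red blood cell markers fell with age in females at 2 of 8 without a call of the list (camera adjusted p = 0.208, and adjusted p = 0.66 with an estimated correlation); HBE1 and HBAD (-0.70, called in 18 of the 22 fits without 1 library) are the members. With the depth term CRYAB (0.0724), UQCRFS1 (0.195) and HBAD (0.458) lost their call in females. With the depth term the red blood cell (adjusted p = 0.0425), steroid and thyroid (0.0257) and cell cycle (0.00602) lists passed for age in males and the ribosomal list (0.00106) for the interaction, tested at camera's preset correlation. In the main fit the 4 lists did not pass, and with an estimated correlation there the adjusted p was 0.641, 0.264, 0.458 and 0.828.

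If the male excess of Z expression is a property of each Z-linked gene, genes with a large fold at 20 days should have a large fold at 50 days. Across 658 Z-linked genes the folds correlated with r = 0.447 (Spearman 0.575), and across 12921 autosomal genes with r = 0.0375 (Spearman 0.151). Measurement noise lowers both, and genes are not independent.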
